A study of Mus musculus with 6 samples.

How the data were processed

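The series holds 6 RNA-seq libraries of C2C12, an immortalised mouse myoblast line. Per the labels, 3 libraries came from control cells and 3 from cells put under cyclic mechanical stretch (MS) on a device that bends the culture plate at 4 points. The stretch is given as 5333 μ, a unit the labels do not spell out, at a plate displacement of 4 mm, for 8 h at 1 Hz. Per the labels' protocols, 5 μg of total RNA with an integrity number above 7.0 was selected with oligo(dT) beads, made into strand-marked libraries with an insert of 300 ± 50 bp, and read as 150 bp pairs. All 6 libraries carry the same batch label.

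The deposited values are FPKM (fragments scaled by transcript length and by the library's total), per the file headers, with 1 value per gene and library. The submitters' processing notes name cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2, edgeR and the genome build mm39, with no role or order. How the authors treated reads that map to several places, which filters they used and whether counting used the strand are not given in the sources used here. The table has 32815 gene rows, of which 3342 are at 0 in every library. It identifies genes by Ensembl ID, and 31077 IDs took a symbol from a GENCODE M21 name table; the other 1738 kept their ID. Coordinates are those of the table. Transcript length and GC content came from the M21 transcripts by gene ID, since that reference is on another build, and were used in no other way.

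FPKM values are not counts, so no count test was run and the sequencing depth of each library is unknown. Low FPKM values of the same gene in different libraries piled up at fixed ratios, which gave the relative normalizing totals of the libraries. These lay between 0.961 and 1.008 of the total of control 1, a span of 4.9%, and the offsets between pairs of libraries lay within 0.0018 of the fitted totals on the log2 scale. FPKM summed over all rows ranged from 298991 in MS 1 to 329968 in control 3.

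Genes with a mean of at least 1 FPKM over the 6 libraries were tested (12028 genes) on log2(FPKM + 1). A linear model with the 2 groups was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment over all tested genes. Every adjusted p of a single gene comes from this limma fit. A gene was called changed at an adjusted p under 0.05, and a second count added a fold change of at least 2. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

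The 39 gene lists were fixed before the data were examined. They cover NAD+ metabolism, contacts between mitochondria and the endoplasmic reticulum, mitochondria, stress responses, mechanical signalling, muscle, cell cycle and metabolism, with markers of 7 other cell types and 1 list of histone transcripts, most of which lack a poly(A) tail (H1f0, on that list, carries a tail). Members were matched by exact symbol. Each list was described by its calls, over all genes and adjusted over the list alone, and the 32 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over those lists. Camera with an estimated correlation and fry, which asks whether the members move on balance to a common side, were run beside it. Camera with an estimated correlation takes its p from the 4 residual degrees of freedom, and the preset setting from nearly as many as the tested genes. Its adjusted p can therefore be large without correlation between the members. Annotation terms paired with genes in the deposited table (GO, KEGG, Reactome) were tested with a one-sided Fisher's exact test for higher and for lower genes, for terms of 10 to 500 tested genes, against all 12028 tested genes. Terms are named only if they also passed against the tested genes that carry any term of that source, a check added later. The text of some annotation cells was not analysed here (2481 rows for GO, 16 for KEGG and 1690 for Reactome).

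The genes named were set by a rule: Sirt1, Mfn2 and Nampt always; the 6 largest fold changes up and down among called genes with a mean of at least 5 FPKM, a regular symbol and groups that do not overlap; up to 3 called members of each main list, or the member with the smallest p where none was called; and up to 2 members of each other list described. Genes named outside this rule are said to be so, and 1 gene that the rule names is not reported here.

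The steps were tested on simulated data with the real means and residual spreads of all 12028 genes. With 200 genes changed, 55 of 67 were recovered at 1.5-fold, 62 of 67 at 2-fold and 63 of 66 at 4-fold, and 4.3% of calls were false. Of 200 unchanged lists of 25 genes, camera gave an unadjusted p under 0.05 for 10 at the preset correlation and for 1 with an estimated correlation. The simulated genes varied independently of each other. These lists therefore cannot show how the preset correlation performs for lists whose genes vary together.

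Alternatives chosen with the design were pseudocounts of 0.1 and 0.25, no low-value filter and a mean of at least 5 FPKM, TMM, median-of-ratios and quantile scaling of the values, other variance models, library weights, the replicate number as a block, and leaving out each library. Count tests were not run because no counts were analysed here. Transcripts of other tissues, described below with the libraries, split the libraries into 3 sets of 2: control 1 with control 2, control 3 with MS 1, and MS 2 with MS 3. These sets follow from whether the summed FPKM of a tongue and salivary list and of a kidney list reached 50. They are not groups of the study and were defined after seeing the data. Alternatives added then were the set as a term of the model, leaving out control 3 and MS 1, leaving out mitochondrial and ribosomal RNA rows with rescaling, and a loess correction for transcript length and GC content (span 0.3; 99.3% of tested genes had both). Only the set of control 3 and MS 1 holds both groups, so the model with the set as a term rests its MS effect on that pair and takes its spread from the other sets, with 2 residual degrees of freedom. Leaving out mitochondrial rows kept the pseudogene copies of mitochondrial genes on chromosome 1. Figures were drawn with matplotlib 3.10.9.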

Results

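Gene expression was measured by poly(A) RNA-seq in C2C12 mouse myoblasts, in 3 control libraries and 3 libraries of cells after 8 h of cyclic mechanical stretch (MS). The series title concerns NAD+ deficiency, mitochondria-endoplasmic reticulum contacts and the Sirt1-MFN2 axis in stress urinary incontinence. The comparison asks which transcripts differ between stretched and control myoblasts. Between 21893 and 23737 genes had a value above 0 per library, and between 11879 and 12093 reached 1 FPKM.

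Stretched cells had more transcripts of heat shock, stress-response and antioxidant genes and fewer of cell division and matrix genes and fewer mitochondrially encoded messenger RNAs. Of 12028 tested genes, 6470 (53.8%) changed at an adjusted p under 0.05, 3683 higher and 2787 lower in MS. Changes of at least 2-fold were found for 621 genes, 209 higher and 412 lower, while 4694 of the changed genes moved by less than 1.5-fold. The values of the 2 groups did not overlap for 7537 genes (62.7%), against 10% by chance for 3 libraries against 3. The median log2 fold change of all tested genes was 0.05.

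The largest increases were in Hspa1a and Hspa1b, the inducible HSP70 chaperones. Hspa1b (chromosome 17, 35175412 to 35178214, mm39) rose from 29.4 ± 0.757 FPKM in control to 571 ± 113 in MS (SD, n = 3 each; log2 fold change 4.22, SE 0.12, adjusted p = 1.06e-05), and Hspa1a (chromosome 17, 35188166 to 35191132) had a log2 fold change of 4.51. The mitochondrial ribosomal RNA mt-Rnr1 rose by 3.78, the glutathione S-transferases Gsta1 and Gsta2 by 3.35 and 2.89, and the carbonic anhydrase Car6 by 3.32. The largest decreases included the rows of the mitochondrial transfer RNAs mt-Tk (-3.75) and mt-Tw (-3.05). The others were in the mitochondrial messenger RNAs mt-Nd3 (-3.15) and mt-Atp8 (-3.07), the mitotic cyclin Ccnb2 (-3.07) and the mitotic kinase Plk1 (-3.01). Most other rows of mitochondrial transfer RNAs were lower too, but mt-Tf (1.02) and mt-Ty (0.49) rose and mt-Tn was at 0.02. These were named after their values were seen. All transfer RNA rows are shorter than the stated library insert, so their fragments may come from longer transcripts that cover them. Where these reads came from was not tested, so the values cannot show whether transfer RNAs themselves changed. Hspa1a and Hspa1b, and likewise Gsta1 and Gsta2, are near-identical copies whose reads the authors' counting could split either way, so each value is uncertain while the pair rose together.

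The libraries grouped by treatment, and control 3 and MS 1 stood apart from the rest. The first principal component held 73.7% of the variance and separated MS from control, and the second (15.3%) separated control 3 and MS 1 from the other libraries. Pearson correlations of log2 values across genes were 0.994 between control 1 and control 2 and 0.994 between MS 2 and MS 3, against 0.98 to 0.982 for control 3 with the other controls and 0.983 to 0.985 for MS 1 with the other MS libraries. Transcripts of tongue and salivary glands summed to 528 FPKM in control 3 and 617 in MS 1, and to between 7.07 and 11.2 in the other libraries. A kidney list summed to between 111 and 122 FPKM in control 3 and all 3 MS libraries, and to 3.9 and 4.48 in control 1 and control 2. Lens crystallins and other lens genes were lowest in control 3 and MS 1, at 307 and 376 FPKM, against 1243 to 1639 in the others. The pair of control 3 and MS 1 is the only set by these transcripts that holds both groups, so the difference MS 1 minus control 3, which has no test of its own, stands beside each gene list with at least 5 tested members. With the set as a term in the model 3166 genes changed, 1845 higher and 1321 lower, and 519 changed at least 2-fold. Without control 3 and MS 1, 6228 genes changed, but each set that remains holds a single group, so this count cannot separate treatment from set.

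**Figure D1:**
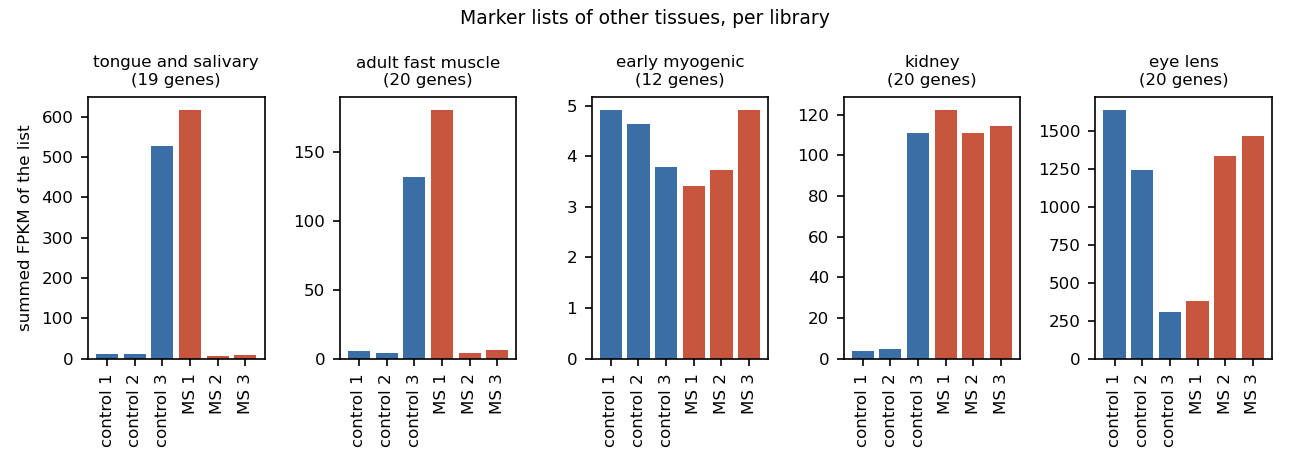
Summed FPKM of marker lists of other tissues (vertical axis) in each library (horizontal axis; blue control, red MS), with a separate scale per list. The tongue and salivary list reaches 528 in control 3 and 617 in MS 1 and at most 11.2 elsewhere, while the kidney list is at 3.9 and 4.48 in control 1 and control 2 and at 111 to 122 in the other libraries.

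Transcripts of Sirt1 and Mfn2, the genes in the series title, and of Nampt did not pass the test. Sirt1, an NAD+-dependent deacetylase (chromosome 10, 63154784 to 63217483, mm39), was at 3.81 ± 0.331 FPKM in control and 4.35 ± 0.345 in MS (SD, n = 3 each), with a log2 fold change of 0.16 (95% interval -0.03 to 0.34, adjusted p = 0.135). Mfn2, a mitofusin of the outer mitochondrial membrane that is also found at contacts with the endoplasmic reticulum (chromosome 4, 147958056 to 147989161), was at 15.1 ± 0.841 FPKM in control and 16.6 ± 0.481 in MS, with a log2 fold change of 0.14 (95% interval 0.01 to 0.26 before adjustment for multiple tests, adjusted p = 0.0712). Every MS library lay above every control library for Mfn2, and it passed the threshold without control 3 (adjusted p = 0.0217) and with library weights (adjusted p = 0.0216), within a range of 0.0216 to 0.442 over its alternatives. Nampt, the rate-limiting enzyme of NAD+ salvage (chromosome 12, 32869544 to 32903348), was at 17.7 ± 0.541 FPKM in control and 17.4 ± 0.91 in MS, with a log2 fold change of -0.03 (95% interval -0.15 to 0.10, adjusted p = 0.72). By the spread between these libraries, the intervals exclude a 2-fold difference between the groups for each of these 3 transcripts. That spread may be technical and the model has no term for the library sets, so a stretch effect in separate cultures is not bounded.

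NAD+ genes and contact genes moved in both directions. Of 14 tested genes of NAD+ synthesis and precursor transport, 3 rose and 6 fell, over all genes and adjusted over the list alone, with a list median of -0.02 (camera adjusted p = 0.342). The mitochondrial NAD kinase Nadk2 fell from 9.39 ± 1.07 to 5.45 ± 0.464 FPKM (log2 fold change -0.68, adjusted p = 0.000813) and the nucleoside transporter Slc29a1 fell by 0.42 on the log2 scale, while Nmnat2, which makes NAD+ from nicotinamide mononucleotide, rose by 0.38. Of 21 NAD+-consuming enzymes 5 rose and 5 fell, over all genes and adjusted over the list alone, among them Parp3 (0.60) and Sirt2 (0.34) upward and Parp9 (-0.45) downward. Their median was 0.09 although the test pointed downward (camera adjusted p = 0.985). Of 41 genes of mitochondria-endoplasmic reticulum contacts, 20 rose and 8 fell, over all genes and adjusted over the list alone, with a median of 0.14 (camera adjusted p = 0.19). The list passed without the low-value filter (adjusted p = 0.032), against adjusted p = 0.569 with an estimated correlation. The set as a term left 6 of its genes higher and 3 lower, 1 and 3 of NAD+ synthesis, and 2 and 2 of the consumers. Its largest changes were in Hspa9, the mitochondrial HSP70 that links VDAC with the IP3 receptor (184 ± 28.3 to 395 ± 26.3 FPKM, log2 fold change 1.10), in Rmdn3, a tether also called PTPIP51 (0.62), and in the IP3 receptor Itpr3 (0.55). Medians of MS 1 minus control 3 were -0.08, 0.08 and 0.14 for the 3 lists.

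**Figure D2:**
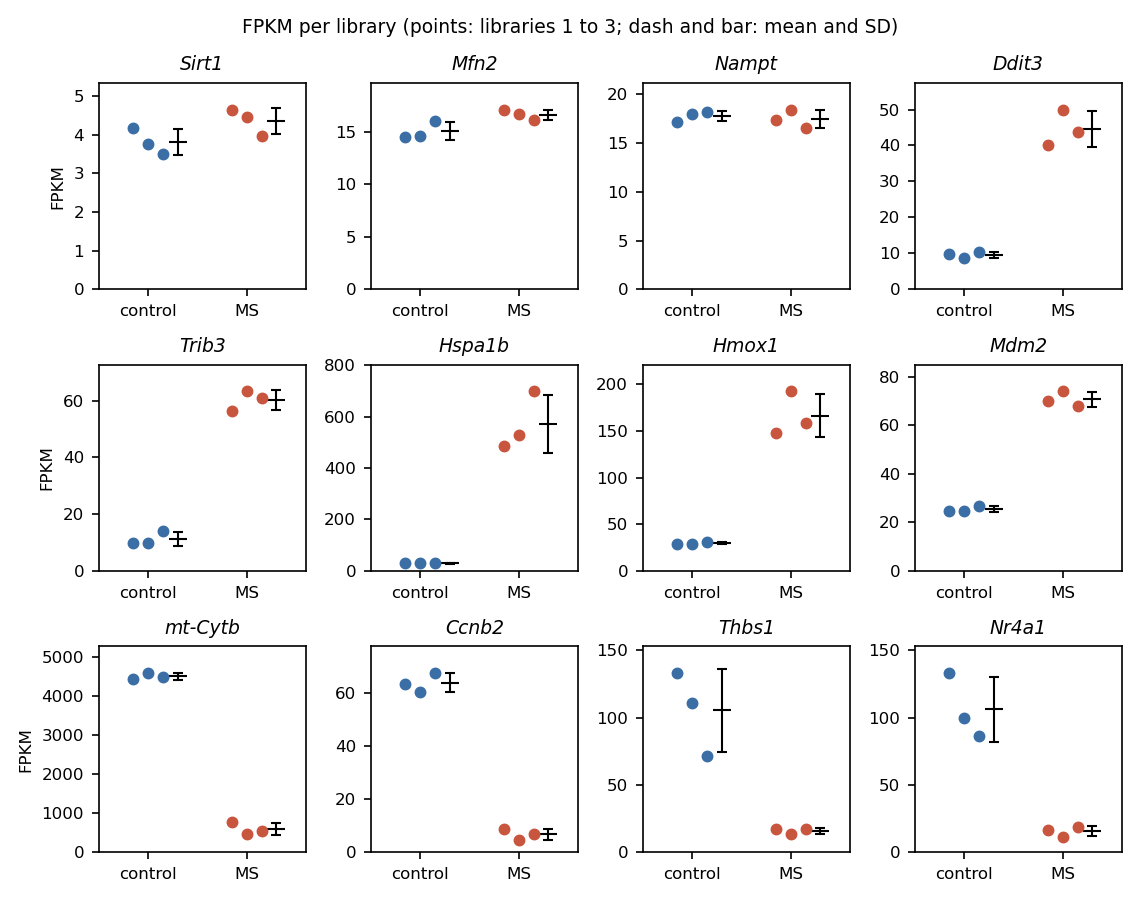
FPKM in each library (points) with the mean and SD (dash and bar) of the 3 control libraries (blue) and the 3 MS libraries (red), for 12 genes, each with its own linear axis from 0. Sirt1 and Nampt overlap between the groups, Mfn2 differs by little, and the other 9 genes are separated in every library.

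Targets of ATF4, the transcription factor of the integrated stress response, rose almost throughout. Of 27 tested members 25 rose and 0 fell, over all genes and adjusted over the list alone, with a median log2 fold change of 1.34 (camera adjusted p = 6.62e-10, and adjusted p = 0.37 with an estimated correlation). The pseudokinase Trib3 rose from 11.2 ± 2.44 to 60.2 ± 3.51 FPKM, the glutathione-degrading enzyme Chac1 from 16.5 ± 3.64 to 80 ± 9.6 and Ddit3, which encodes CHOP, from 9.59 ± 0.846 to 44.6 ± 4.97 (SD, n = 3 each). Log2 fold changes were 2.34 for Trib3 and 2.23 for Chac1. Of the 16 lists past the threshold at the preset correlation, 0 passed with an estimated correlation. The list's median for MS 1 minus control 3 was 1.11. Genes of the endoplasmic reticulum unfolded protein response divided, with 13 of 28 higher and 11 lower (14 and 12 adjusted over the list alone; median 0.08, camera adjusted p = 0.925). Wfs1 (1.01), Herpud1 (0.95) and the HSP70 co-chaperone Dnajb9 (0.64) had its largest changes, all upward, and the median for MS 1 minus control 3 was 0.10. Calls with the set as a term were 8 higher and 3 lower for this list, and 25 and 0 for ATF4 targets.

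All 13 mitochondrially encoded messenger RNAs fell, over all genes and adjusted over the list alone. Their median log2 fold change was -2.74 (camera adjusted p = 6.62e-10, and adjusted p = 0.37 with an estimated correlation), and their median for MS 1 minus control 3 was -2.34, with all 13 lower with the set as a term. Cytochrome b, mt-Cytb, went from 4508 ± 82.3 FPKM in control to 596 ± 159 in MS (log2 fold change -2.95, adjusted p = 2.3e-05), mt-Atp8 from 5527 ± 117 to 676 ± 196 and mt-Nd3 from 187 ± 20.3 to 20.6 ± 5.85 (SD, n = 3 each). These messenger RNAs took 12.4% to 13.4% of summed FPKM in the control libraries and 1.64% to 2.82% in the MS libraries. Both mitochondrial ribosomal RNAs rose, mt-Rnr1 from 88.4 ± 13.8 to 1226 ± 181 FPKM and mt-Rnr2 from 417 to 1006 on average, the latter named after its values were seen. Ribosomal RNA rows together took 0.646% to 0.797% of summed FPKM in control and 2.27% to 4.94% in MS, and 1 nuclear ribosomal RNA row, named by its ID ENSMUSG00000119584 (chromosome 17, 40157244 to 40159092), ranged from 1525 to 2128 FPKM in control and from 4793 to 12353 in MS. A stretch of chromosome 1 from 24650616 to 24655278 carries 7 pseudogene copies of mitochondrial genes, and all 7 fell by similar amounts, with log2 fold changes from -3.14 to -2.24. The way reads were divided between these copies and the mitochondrial genes is not given in the sources used here. The copy Gm28437 and mt-Co3, named after their values were seen, were nearly equal in every library. They were at 3268 and 3277 FPKM in control 1 and at 656 and 657 in MS 1. Such values can come from the same reads, so the fall of the copies is no separate observation.

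**Figure D3:**
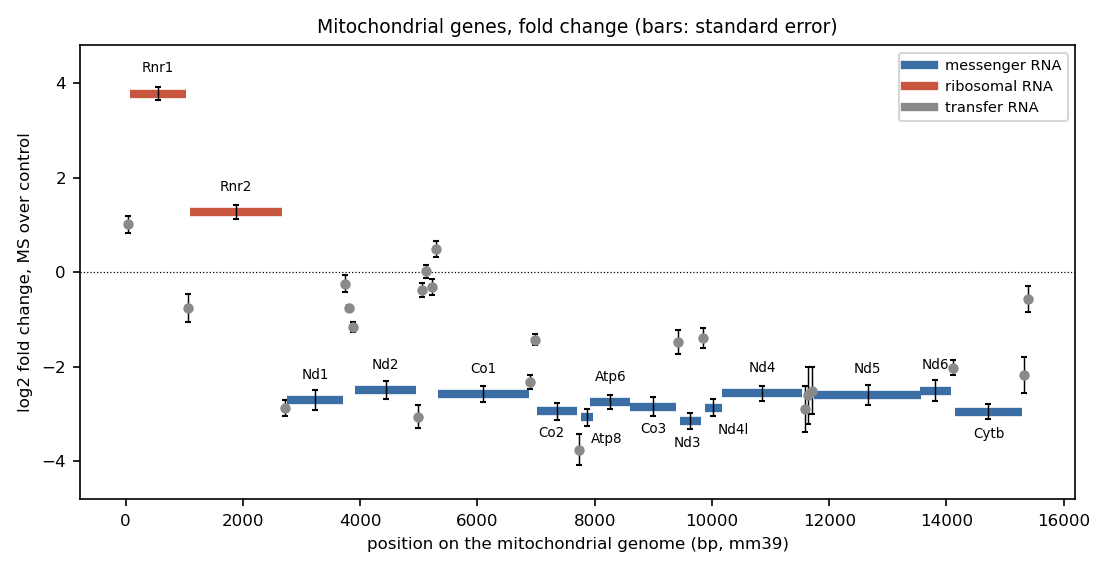
Log2 fold change of MS over control (vertical axis) along the mitochondrial genome (horizontal axis, bp, mm39) for tested mitochondrial genes, with horizontal bars or points for each gene's extent and vertical bars for its standard error. All 13 messenger RNAs lie between -3.15 and -2.49, while mt-Rnr1 is at 3.78 and mt-Rnr2 at 1.27.

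Nuclear genes of mitochondria did not share this fall. Of 75 nuclear-encoded subunits of oxidative phosphorylation, 21 rose and 3 fell (16 and 0 adjusted over the list alone), with a median of 0.09 (camera adjusted p = 0.221) and the largest changes in Uqcrq (0.61), Uqcrc2 (0.41) and Ndufs4 (0.37), the last of which was at 0.22 with the set as a term and lost its call (adjusted p = 0.207). Mitochondrial chaperones and proteases rose in 13 of 14 members (13 higher and 1 lower adjusted over the list alone), with a median of 0.40 (camera adjusted p = 0.000348, and adjusted p = 0.433 with an estimated correlation). The matrix protease Lonp1 went from 47.7 ± 3.98 to 123 ± 2.91 FPKM (log2 fold change 1.35). The set as a term left 6 of the chaperones and proteases higher and 0 lower, and 7 and 1 of the oxidative phosphorylation subunits, 2 and 1 of the fusion and fission genes, and 2 and 0 of the biogenesis regulators. Fusion and fission genes had 6 of 20 higher and 1 lower, over all genes and adjusted over the list alone (median 0.12, camera adjusted p = 0.238): Mtfr1l (0.62) and Mief1 (0.40) rose and Mtfr2 (-1.19) fell, and Mief1 was at 0.27 with the set as a term and lost its call (adjusted p = 0.0913). Among regulators of mitochondrial biogenesis 7 of 17 rose and 3 fell (7 and 4 adjusted over the list alone; median 0.18, camera adjusted p = 0.285), with Twnk, the mitochondrial helicase, at 0.60, the receptor Esrra at 0.54 and the transcription factor Tfb2m at 0.43, which with the set as a term kept a fold change of 0.44 while its SE went from 0.08 to 0.15 and its call was lost (adjusted p = 0.0799). Medians for MS 1 minus control 3 were 0.07, 0.25, 0.06 and 0.11 for these 4 lists, in this order.

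Cytosolic chaperones, antioxidant genes and p53 targets rose together. Cytosolic heat shock chaperones were higher for 14 of 19 members and lower for 1 (14 and 2 adjusted over the list alone), with a median of 0.59 (camera adjusted p = 0.000147, and adjusted p = 0.37 with an estimated correlation). NRF2 targets and antioxidant enzymes were higher for 23 of 27 and lower for 1, over all genes and adjusted over the list alone, with a median of 0.54 (camera adjusted p = 3.54e-07, and adjusted p = 0.37 with an estimated correlation). Heme oxygenase, Hmox1, rose from 29.7 ± 1.29 to 166 ± 23.2 FPKM and the glutathione S-transferase Gsta4 from 54.5 ± 4.25 to 289 ± 32.7. Of 23 p53 targets 19 rose and 1 fell (19 and 2 adjusted over the list alone), with a median of 0.67 (camera adjusted p = 7.98e-06, and adjusted p = 0.205 with an estimated correlation). Gdf15, a secreted stress factor that is also an ATF4 target, rose by 1.95 on the log2 scale and Mdm2, the ubiquitin ligase of p53, rose from 25.3 ± 1.25 to 70.6 ± 3.03 FPKM. Autophagy and mitophagy genes were higher for 17 of 29 and lower for 2 (18 and 2 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 0.00321, and adjusted p = 0.37 with an estimated correlation). The autophagy receptor Sqstm1 rose from 205 ± 7.09 to 830 ± 71.4 FPKM and Atg7 by 0.93 on the log2 scale. Apoptosis regulators moved both ways, 10 of 30 higher and 8 lower over all genes and adjusted over the list alone (median -0.02, camera adjusted p = 0.623). Bbc3, which encodes PUMA, rose (0.76), Birc5, a survivin that is also a mitotic gene, fell (-2.21), and Bmf fell (-0.87), a call lost with the set as a term (-0.19, adjusted p = 0.457) and without control 1, control 2, MS 2 or MS 3 (-0.93 to -0.69, adjusted p from 0.0505 to 0.0799). The Bmf call was also lost without the low-value filter (adjusted p = 0.093). Medians for MS 1 minus control 3 were 0.47, 0.51, 0.69, 0.41 and 0.07 for heat shock, NRF2, p53, autophagy and apoptosis. Higher and lower calls with the set as a term were 12 and 1, 19 and 0, 17 and 0, 15 and 1, and 5 and 2 for these lists, in this order.

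Genes of cell division fell as a group. All 26 tested G2/M and mitosis genes were lower in MS, over all genes and adjusted over the list alone, with a median log2 fold change of -2.24 (camera adjusted p = 2.07e-17, and adjusted p = 0.37 with an estimated correlation). Ccnb2 went from 64 ± 3.53 to 6.92 ± 2.06 FPKM and Plk1 from 59.3 ± 4.82 to 6.7 ± 2.28 (SD, n = 3 each). Of 26 G1/S and DNA replication genes 25 fell and 0 rose, over all genes and adjusted over the list alone, with a median of -0.72 (camera adjusted p = 1.26e-11, and adjusted p = 0.37 with an estimated correlation). Rrm2 and Rrm1, the subunits of ribonucleotide reductase, fell by 1.59 and 1.31 on the log2 scale. Medians for MS 1 minus control 3 were -2.14 for G2/M and -0.80 for G1/S, and 26 and 23 genes of these lists were called lower, and 0 higher, with the set as a term.

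Target genes of mechanical signalling and matrix genes were mostly lower after stretch. Of 20 YAP/TEAD targets 14 fell and 2 rose, over all genes and adjusted over the list alone (median -0.29, camera adjusted p = 0.00138, and adjusted p = 0.392 with an estimated correlation). Ccn1, a matricellular protein, fell from 373 ± 59.6 to 118 ± 13.9 FPKM and Ccdc80 by 1.40 on the log2 scale, while Gadd45a, which is also a stress gene, rose from 38.1 ± 7.33 to 95 ± 7.69 FPKM. SRF/MRTF targets of the cytoskeleton fell for 16 of 27 and rose for 5, over all genes and adjusted over the list alone (median -0.22, camera adjusted p = 0.0226, and adjusted p = 0.569 with an estimated correlation). Smooth muscle actin, Acta2, fell from 94.9 ± 6.09 to 30.7 ± 2.8 FPKM, Filip1l by 1.06 and Myl9 by 0.86 on the log2 scale, the last of which was at -0.63 with the set as a term, with an SE of 0.30 against 0.17, and lost its call (adjusted p = 0.178). The set as a term left 1 YAP/TEAD target higher and 5 lower, and 3 and 8 of the SRF/MRTF targets. Extracellular matrix genes fell for 31 of 45 and rose for 5 (33 and 6 adjusted over the list alone), with a median of -0.58 (camera adjusted p = 2.05e-07, and adjusted p = 0.433 with an estimated correlation). The thrombospondins Thbs1 and Thbs2 and the collagen Col12a1 had log2 fold changes of -2.60, -1.75 and -1.69. Of 30 immediate-early genes 17 fell and 9 rose, over all genes and adjusted over the list alone, with a median of -0.52 (camera adjusted p = 0.0533). The nuclear receptor Nr4a1 fell from 106 ± 24.1 to 15.9 ± 3.71 FPKM, Fos from 106 ± 28.3 to 32.4 ± 3.94 and Egr2 by 1.42 on the log2 scale. The immediate-early list passed without control 3 (adjusted p = 0.0201) and without MS 3 (adjusted p = 0.0239), against adjusted p = 0.637 with an estimated correlation. Its calls with the set as a term were 6 higher and 11 lower. Mechanosensitive and calcium channels were higher for 5 of 15 and lower for 4, over all genes and adjusted over the list alone (median -0.04, mean 0.05, camera adjusted p = 0.925), with Orai2 (0.51) and Tmem63b (0.50) the largest. Medians for MS 1 minus control 3 were -0.26, -0.13, -0.37, -0.35 and 0.03 for YAP, SRF, matrix, immediate-early and channel genes. Matrix genes had 2 higher and 21 lower calls with the set as a term, and channel genes 3 and 0.

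**Figure D4:**
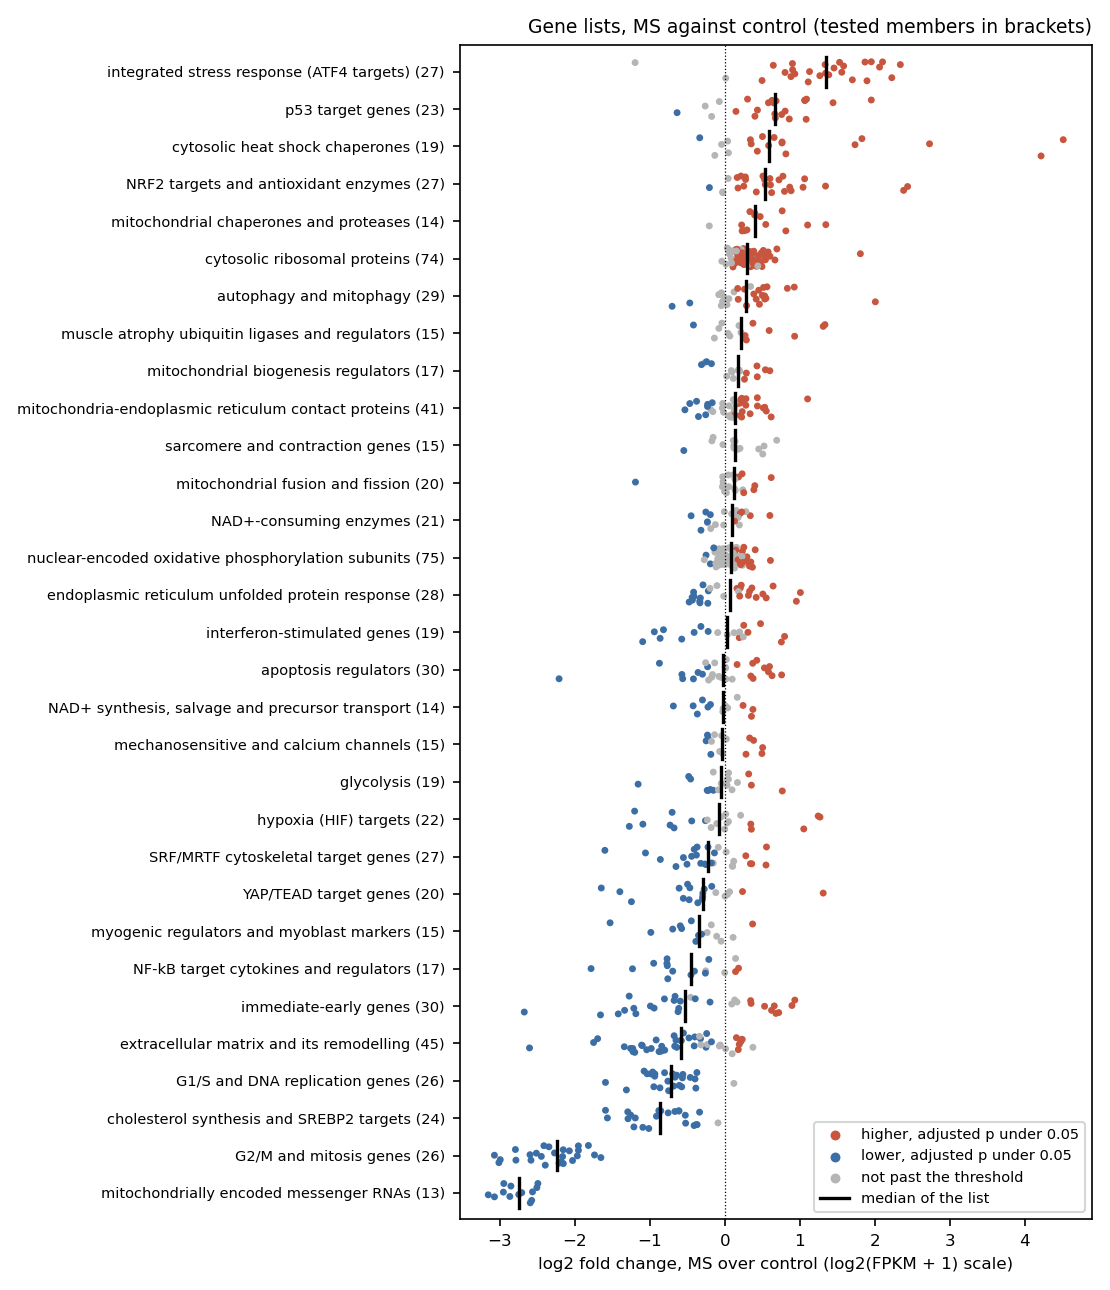
Log2 fold change of MS over control (horizontal axis) of every tested member (points) of the gene lists with at least 5 tested members (vertical axis, histone list not drawn), coloured by whether the member passed the test, with the list median as a black bar. Medians run from -2.74 for mitochondrially encoded messenger RNAs to 1.34 for ATF4 targets.

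Myogenic regulators were mostly lower in the comparison of all libraries, and sarcomere genes depended on the library. Of 15 tested myogenic regulators and myoblast markers 9 fell and 1 rose (11 and 1 adjusted over the list alone), with a median of -0.35 (camera adjusted p = 0.00321, and adjusted p = 0.49 with an estimated correlation). Some members of the list had low values: Myod1 lay between 0.82 and 2 FPKM over the libraries and Myf5 between 1.63 and 2.5. Myog was at most at 0.31, while Des was at 46.7 to 59.8. These genes were named after their values were seen. Id3, an inhibitor of myogenic bHLH factors, fell from 24.9 ± 6.28 to 7.96 ± 1.99 FPKM, and Vcam1 by 0.69 on the log2 scale. The set as a term left 3 of the 15 lower and 2 higher, and Id3 was then at -0.86 and lost its call (adjusted p = 0.053). Of 15 tested sarcomere genes 1 fell, Actn3 (-0.55), and 0 rose, over all genes and adjusted over the list alone. That call was also lost with the set as a term (-0.34, adjusted p = 0.072). The list's median was 0.13 although the test pointed downward (camera adjusted p = 0.89), and it ranged from -1.04 to 1.17 when single libraries were left out. With the set as a term the test pointed upward (median 0.40, adjusted p = 0.0396), against adjusted p = 0.985 with an estimated correlation. Adult muscle transcripts such as Acta1, named after its values were seen, were at 24.6 FPKM in control 3 and 33.9 in MS 1 and at 0.688 to 1.22 in the other libraries. Muscle atrophy genes rose in 7 of 15 and fell in 1, over all genes and adjusted over the list alone (median 0.22, camera adjusted p = 0.0632), led by Klf15 (1.34) and Gadd45a (1.31); without MS 2 the list passed (adjusted p = 0.0415), against adjusted p = 0.433 with an estimated correlation. Medians for MS 1 minus control 3 were -0.21, 0.40 and 0.31 for these lists, and the sarcomere and atrophy lists had 2 and 7 higher and 0 lower calls with the set as a term.

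Cholesterol synthesis fell and ribosomal protein genes rose. Of 24 genes of cholesterol synthesis and SREBP2 targets 23 fell and 0 rose, over all genes and adjusted over the list alone, with a median of -0.86 (camera adjusted p = 6.48e-13, and adjusted p = 0.37 with an estimated correlation). Insig1, the sterol-sensing retention protein, fell from 52.2 ± 5.54 to 16.9 ± 3.74 FPKM and the sterol carrier Stard4 from 10.6 ± 0.855 to 2.94 ± 0.437. Ribosomal protein genes rose for 59 of 74 and fell for 0, over all genes and adjusted over the list alone, by a median of 0.30 (camera adjusted p = 9.68e-10, and adjusted p = 0.37 with an estimated correlation). Of these, 32 were higher and 0 lower with the set as a term. Rpl17 (1.81, SE 0.38) and Rpl38 (0.69) had the largest changes, and reads of such genes can be shared with processed pseudogenes. NF-kB targets fell for 12 of 17 and rose for 2 (13 and 2 adjusted over the list alone), with a median of -0.45 (camera adjusted p = 0.000186, and adjusted p = 0.37 with an estimated correlation). The chemokine Cxcl5 fell from 286 ± 23.4 to 83.2 ± 14.2 FPKM and the cytokine Lif from 8.43 ± 0.432 to 3.02 ± 0.0513. Interferon-stimulated genes were 6 higher and 8 lower of 19 (7 and 8 adjusted over the list alone; median 0.03, mean -0.10, camera adjusted p = 0.342), with the immunoproteasome subunits Psmb9 (-1.09) and Psmb8 (-0.94) lower. With the set as a term 0 of them were higher and 5 lower, and the list passed downward (median -0.18, adjusted p = 0.0229), against adjusted p = 0.569 with an estimated correlation. Glycolysis genes were 3 higher and 7 lower of 19 (median -0.05, camera adjusted p = 0.342) and hypoxia targets 5 higher and 8 lower of 22 (median -0.08, camera adjusted p = 0.254), with the same counts adjusted over the list alone. The lactate transporter Slc16a3 (-1.15) and Car9 (-1.27) fell, and the hexokinase Hk2 (0.77) and Ndrg1 (1.27) rose. Medians for MS 1 minus control 3 were -0.74, 0.24, -0.44, -0.18, -0.05 and 0.05 for cholesterol, ribosomal, NF-kB, interferon, glycolysis and hypoxia genes. Calls with the set as a term were 0 higher and 18 lower for cholesterol, 0 and 10 for NF-kB, 3 and 5 for glycolysis and 5 and 7 for hypoxia genes.

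Annotation terms gave the same division between growth machinery and the cell cycle. Of 1714 GO terms, 67 passed for higher and 138 for lower genes. Higher genes were enriched for translation, with 172 of 266 tested genes against 81.4 by chance (one-sided Fisher's exact test, adjusted p = 1.12e-27). Lower genes were enriched for cell cycle, with 172 of 374 against 86.7 (adjusted p = 9.57e-20), for DNA replication, with 64 of 98 against 22.7 (adjusted p = 2.5e-16), and for extracellular matrix, with 54 of 84 against 19.5 (adjusted p = 2.25e-13). These tests treat genes as independent, which co-regulated genes are not.

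Markers of other cell types were mostly under the 1 FPKM minimum. Of macrophage markers 3 of 12 were tested: Cd68, which is also a lysosomal protein, rose from 4.21 ± 0.788 to 26.9 ± 2.56 FPKM, Cd14 fell (-0.24), and Lyz2, named outside the rule, did not pass. Of 9 endothelial markers 0 were tested. The keratins Krt18 and Krt8 rose by 1.68 and 1.25 on the log2 scale, but Krt18 was at 0.801 FPKM in MS 1 and at 4.56 and 4.72 in MS 3 and MS 2, and both calls were lost with the set as a term (0.10 and 0.17, adjusted p = 0.628 and 0.477). Krt18 also lost its call without control 1, control 2, MS 2 or MS 3 (1.39 to 1.57, adjusted p from 0.0545 to 0.0626). Of 4 tested adipocyte markers Pparg rose (0.69) and Cebpa fell (-1.07), and of 3 tested bone and cartilage markers Dmp1 fell (-1.36). Both tested fibroblast markers, Ly6a (-0.60) and Pdgfra (-0.37), fell. Of 3 tested neural markers Tubb3 rose (0.46) and Syt1 fell (-0.33). Calls of Cd14, Cebpa, Ly6a, Tubb3 and Syt1 were lost with the set as a term (-0.05, -0.43, -0.26, 0.29 and -0.17, adjusted p from 0.0653 to 0.702). Cd14 also lost its call without control 1, control 2, MS 2 or MS 3 (-0.24 to -0.19, adjusted p from 0.0614 to 0.0795) and Syt1 without control 2, control 3, MS 2 or MS 3 (-0.34 to -0.28, adjusted p from 0.0504 to 0.0862). Without the low-value filter Krt8, Krt18, Cd14 and Syt1 lost their calls too (adjusted p from 0.058 to 0.0757), as did Syt1 with the replicate number as a block (adjusted p = 0.0555). Of 6 tested members of the histone list, most without a poly(A) tail, 2 rose, Hist2h2aa1 (1.01) and Hist1h2bc (0.72), and 1 fell, over all genes and adjusted over the list alone (median 0.04, camera adjusted p = 0.985). The call of Hist2h2aa1 was lost in 11 of 18 alternatives, with fold changes from 0.15 to 2.68 and adjusted p from 0.000405 to 0.679. The median for MS 1 minus control 3 of this list was 0.24, and 2 members were higher and 0 lower with the set as a term.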

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

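The set as a term, leaving out control 3 and MS 1 together, leaving out mitochondrial and ribosomal RNA and the length and GC correction were chosen only after the data were seen; the other alternatives were set before the data were examined. With those, all 68 counts stayed within 1.5 times, from 4741 changed genes at a mean of at least 5 FPKM to 7221 with library weights, and changes of at least 2-fold ranged from 467 to 880. Leaving out single libraries gave 5385 to 6491 changed genes, 3074 to 3634 higher, 2283 to 2857 lower and 573 to 702 changed at least 2-fold. Higher genes made up 56.9% of changed genes, 50.3% after TMM and 49.3% after median-of-ratios scaling, so the excess of higher genes depends on the scaling. With the set as a term 3166 genes changed (1845 higher, 1321 lower), of which 2948 were called in the same direction without it; that model has 2 residual degrees of freedom instead of 4.

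With an estimated correlation each of the 16 called lists lost its call. Their medians, which this setting leaves as they are, were -2.744 (mitochondrially encoded), -2.238 (G2/M), -0.865 (cholesterol), -0.72 (G1/S), -0.58 (matrix), -0.45 (NF-kB), -0.349 (myogenic), -0.295 (YAP), -0.223 (SRF), 0.29 (autophagy), 0.301 (ribosomal proteins), 0.401 (mitochondrial chaperones), 0.541 (NRF2), 0.585 (heat shock), 0.668 (p53) and 1.343 (ATF4). Adjusted p ranged from 0.205 to 0.569. The estimate, from 4 residual degrees of freedom, reached 0.978 for mitochondrially encoded genes, and a higher correlation widens the test by construction. This setting also takes its p from those 4 degrees of freedom, and the preset one from nearly as many as the tested genes. That raises p without any correlation between members. For p53 targets the estimate was -0.01 against the preset 0.01, so a higher correlation cannot account for their change. Their camera adjusted p went from 7.98e-06 to 0.205.

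Other lists gained a call. Fry, which tests another hypothesis, called lists of median -0.046 (glycolysis), -0.024 (NAD+ synthesis), 0.034 (interferon), 0.075 (unfolded protein response), 0.088 (oxidative phosphorylation), 0.124 (fusion and fission), 0.136 (contacts), 0.18 (biogenesis) and 0.216 (atrophy). Without the low-value filter, calls were gained at 0.088 (oxidative phosphorylation), 0.127 (contacts), 0.19 (atrophy) and -0.393 (immediate-early), and with quantile normalization at -0.555 (immediate-early). With the set as a term calls were gained at 0.312 (atrophy), -0.177 (interferon) and -0.347 (immediate-early), and the sarcomere list reversed to a call upward at 0.396; after the length and GC correction the atrophy list was called at 0.209. The sarcomere call rests on MS 1 against control 3, where the adult muscle list summed to 181 and 132 FPKM, against at most 6.23 elsewhere. It cannot be told apart from a difference in those transcripts. Without single libraries the atrophy list ranged from 0.195 to 0.255, called without MS 2, and immediate-early genes from -0.602 to -0.37, called without control 3 or MS 3. Except for fry, the causes of these changes were not tested. How far the correlation and the degrees of freedom each account for the losses with an estimated correlation was not tested either.

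Replicates with the same number had correlations of deviations of -0.334, 0.245 and -0.372. The largest was between control 3 and MS 1 (0.456), which share a library set. These values therefore cannot show whether the numbers mark pairs, and the labels do not say. With the replicate number as a block 5890 genes changed, 5758 of them called in the same direction without it. Of the named genes' values under these alternatives, 1579 kept their direction and side of the threshold, 31 lost a call and 2 gained it; under those chosen later 361 kept it and 16 lost it. Count tests were not applicable to FPKM. Sequencing depth is unknown, so its limit on low values is too.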

Other observations

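The tests of other-tissue transcripts, of the library sets, of the mitochondrial genome and of transcript length and GC content below were chosen only after the data were seen, and the genes named beside annotation terms were picked after their values were seen. Higher genes in MS were enriched for the lysosome, with 60 of 106 tested genes against 32.5 by chance and 11 lower (one-sided Fisher's exact test, adjusted p = 1.19e-06; median 0.22, and 0.26 for MS 1 minus control 3; 45 called with the set as a term). Proton pumps of the vacuolar type were higher in 15 of 17 (adjusted p = 6.89e-05), with a median log2 fold change of 0.69 and of 0.67 for MS 1 minus control 3; the subunit Atp6v1h rose from 6.4 ± 0.511 to 16 ± 1.64 FPKM. The proteasome was higher in 42 of 51 and lower in 4 (adjusted p = 6.04e-12; median 0.37, and 0.29 for MS 1 minus control 3; 23 called higher with the set as a term), with the subunit Psmd11 at a log2 fold change of 0.93. Ribosome biogenesis was higher in 68 of 89 and lower in 1 (adjusted p = 1.93e-16), among them Nop14 (1.06) and Utp4 (1.01), but with the set as a term 24 genes of the term were called higher, and the median went from 0.41 to 0.24 for MS 1 minus control 3.

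Mitochondrial translation, encoded in the nucleus, was higher in 51 of 90 and lower in 2 (adjusted p = 1.91e-05, median 0.24), among them Mrps18b (0.90). Of the 90, 14 were called higher with the set as a term, and the median for MS 1 minus control 3 was 0.15. Lower genes were enriched for the Fanconi pathway of DNA repair, with 30 of 48 against 11.1 by chance and 5 higher (adjusted p = 4.87e-07; median -0.42, and -0.38 for MS 1 minus control 3; 22 called with the set as a term), among them Brca1 (-1.04) and Usp1 (-0.87). Collagen trimers were lower in 21 of 27 and higher in 3 (adjusted p = 2.77e-07), with Col1a1 falling from 41.5 ± 6.21 to 16.8 ± 2.07 FPKM. Of the 27, 12 were called lower with the set as a term, and the median went from -0.64 to -0.39 for MS 1 minus control 3.

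Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many changed, higher, lower and 2-fold changed genes as the study's groups, the real split itself (6470, 3683, 2787 and 621). The highest of the other splits was 0 by limma for all 4 counts, with at most 306 genes at an unadjusted p under 0.05 against 7168 in the real split. The other splits each mix the groups, so the difference between the groups enters their spread, and their counts do not measure chance. With 10 splits the share is never under 0.05.

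Genes on the marker lists of other mouse tissues had values in every library: lens genes summed to 307 to 1639 FPKM and were lowest in control 3 and MS 1, where tongue and salivary genes were high. For the latter, that stretch switches them on is argued against, since the tongue and salivary sum in control 3 was 0.855 times that in MS 1. Muscle differentiation in 2 cultures is argued against too: the adult muscle list, which summed to 132 and 181 FPKM in control 3 and MS 1 and to at most 6.23 elsewhere, was higher there by a median log2 of 2.31 (quartiles 0.70 to 3.38), and the embryonic list by -0.039 (quartiles -0.165 to 0.018). RNA or reads of tongue and salivary gland may have entered during library making or sequencing. Of the detected tongue and salivary genes, 13 of 14 (92.9%) were at least 4-fold higher in control 3 and MS 1. Lipf, named after its values were seen, led them (272 and 319 FPKM against at most 0.27 elsewhere). But the list was drawn up after seeing these libraries, so this cannot be told apart from other sources. Lens and kidney transcripts were not tested, so whether they came from other tissues or from the cultured cells is not known. A test would be to look for strain variants in these reads.

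The fall of the 13 mitochondrial messages was weighed against 3 explanations. Dilution by ribosomal RNA reads as the whole cause is argued against, since the median of tested genes off the mitochondrial genome was 0.05 (quartiles -0.191 to 0.265). The library set as the whole cause is argued against by a median of -2.337 for MS 1 minus control 3. The measured values of mitochondrial transcripts did not fall equally, since mt-Rnr1 rose by 3.779. But the nuclear ribosomal RNA row ENSMUSG00000119584 rose too (2.275), so more ribosomal RNA may have passed the poly(A) selection in MS. The rise of mt-Rnr1 therefore cannot decide whether the cells lost all mitochondrial transcripts equally. Open, as a hypothesis, is that stretched cells made or kept fewer mitochondrial messages, and so is a difference in poly(A) selection or in mitochondrial poly(A) tails, which may lower tailed messages while ribosomal RNA rises. Total RNA without poly(A) selection, with mitochondrial DNA copy number, would test these.

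ATF4 targets rose while G2/M genes fell. The library set as the whole cause is argued against by medians for MS 1 minus control 3 of 1.106 for ATF4 targets and -2.143 for G2/M genes, and transcript length and GC content by medians of 1.319 and -2.273 after correction. With the set as a term ATF4 targets held 25 higher and 0 lower calls, and G2/M genes 0 higher and 26 lower. A hypothesis is that 8 h of stretch induced the integrated stress response together with a halt of the cell cycle, which may also follow from a difference in culture density or handling between the groups that the labels do not describe. Protein levels of ATF4 and CHOP with and without an inhibitor of the response, beside cell counts, would test it.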
